A study of Drosophila melanogaster with 3 samples.

How the data were processed

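The measurement was chromatin immunoprecipitation followed by sequencing in whole Drosophila melanogaster embryos aged 0 to 24 h, males and females pooled, from a transgenic line that stably expresses Hsf with GFP at its C terminus. Per the labels, chromatin was sheared by sonication to a size range of 200 to 800 bp, an antibody against GFP was used for the precipitation, and the 3 samples are biological replicates 1, 2 and 3. All 3 samples form 1 group, so no contrast between groups was tested. A control experiment is named in the labels and was not used here as a separate measurement.

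The authors processed the reads and deposited lists of regions in narrowPeak format, in dm6 and in dm3. For each replicate and for the pooled replicates, the deposited list holds the peaks and background regions that entered IDR (irreproducible discovery rate, a test of whether regions rank alike between replicates), with at most 30000 regions in each list. A further deposited list holds the optimal peaks that passed IDR. The signal of each region is the authors' peak score against a control, on a scale of its own in each list. It was therefore used only to rank, filter or describe regions within a list, and it is printed without replicate error. The deposited lists also carry a −log10 q value per region, which reached its ceiling of 4.12 in all 5756 optimal peaks and in 6603 of the 30000 pooled regions, and which was therefore not used to rank. The aligner, the peak caller and their versions are not given in the sources used here. Read counts and read length are not part of the lists used here, so the depth of each sample is unknown and no precision per region can be given from it. The 95% confidence intervals of shares (Wilson) and of odds ratios (exact, conditional) cover counting error over regions or genes only, not differences between embryos or libraries.

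The dm6 lists were the basis of every result, and the dm3 lists were counted separately without converting coordinates. The gene models were those of Ensembl release 115 (annotation 6.54) on genome release 6, whose 6 arms X, 2L, 2R, 3L, 3R and 4 contain the listed positions, apart from 2 regions on Y in the list of replicate 2. The background was the set of 23208 pooled candidate regions on these arms that overlap no optimal peak, that is, regions that entered IDR and did not pass. The optimal peaks were exactly the 5756 pooled regions with the highest signal, so this comparison also sets strong regions against weaker ones. A summit within 500 bp of an annotated transcription start site (TSS) was called a promoter summit. Other summits were assigned in the order 5' UTR, coding sequence, 3' UTR, exon of a noncoding transcript, intron and intergenic. Overlap between replicates was counted at 1 bp or more among each replicate's N strongest regions, N = 5756, and set beside 100 circular shifts of 1 list along each arm. Agreement of signal was described by Spearman's rho across optimal peaks, which are not independent replicates, so no p was computed.

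Motifs were searched on both strands within 100 bp on each side of each summit. The heat shock element was written as GAANNTTCNNGAA, with at most 1 mismatch among its 9 fixed bases, and 20 motifs with the columns of the element permuted gave the level for other motifs of the same bases. The 7 comparison motifs were those of GAGA factor (GAGAGAG), Zelda (CAGGTAG), DREF (TATCGATA), M1BP (GGTCACACT, at most 1 mismatch), the TATA box (TATAAAA), the E-box (CACGTG) and CTCF (CCASYAGRKGG). Shares were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 7 location classes, the 6 arms, the 7 motifs and the 17 gene lists, and a threshold of 0.05. The trend of the element with signal was tested by a permutation test with 100000 resamples.

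The 17 gene lists covered heat shock inducible genes, other chaperones, the proteasome, cytosolic ribosomal proteins, oxidative and metal stress, segmentation, Hox, ecdysone response, muscle, neuronal, germline, chorion and yolk, chemoreceptor, antimicrobial peptide, autophagy, cell cycle and tRNA genes. All symbols of these lists matched the annotation. A gene was counted as having an optimal peak in the list tests when an optimal summit lay within 500 bp of one of its TSSs, and the background was the 9089 genes with any pooled candidate summit within that distance, of the 17947 annotated. The genes named were every heat shock inducible gene, Hsf itself, the genes with the TSS nearest to the 20 strongest optimal peaks, the 4 members with the highest signal of each list that passed its test, and up to 2 such members of each other list. The lists, the tests, this rule and the alternatives were fixed before the data were examined, except for those named below as chosen after seeing the data.

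The alternatives fixed in advance were the optimal peaks above their median signal, those found in the top N of all 3 replicates or of both remaining replicates after leaving out each replicate in turn, promoter or TSS windows of 200 and 1000 bp, 10 random positions per peak, all annotated genes as background, 50 and 250 bp on each side of the summit, no mismatch in the element, candidates matched to the peaks in bins of 2 percentage points of GC content and on promoter class, windows 1000 bp from the summits, other rules of overlap and the dm3 lists. Alternatives chosen after seeing the data were the candidates next in signal below the optimal peaks, as many as there are peaks, and a Mantel-Haenszel common odds ratio over strata of GC content and promoter class with the Cochran-Mantel-Haenszel test. For the copies of Hsp70, the share of 50-mers within 250 bp of each TSS that occur once in the genome was counted. For a search of words outside the motifs, 9-base words within 50 bp of the summits were ranked on the arms X, 2L and 2R against matched candidates, and the 10 highest were tested on the other arms.

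The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, with seed 11. The statistics were tested on simulated data. With the element written into 10% of base-shuffled windows, 15.1% held it against 4.77% of shuffled background windows (odds ratio 3.54). With none written in, 5.68% of shuffled peak windows held it and the odds ratio was 1.20, the level that base composition alone gives. A list of regions with 70% kept in place had an overlap of 72.0%. Of 100 shuffles of the promoter labels, 3 passed the threshold. Simulated gene lists of 30 genes with true odds of 3 had a median odds ratio of 3.02. They were called in 84.5% of draws, and lists of 80 genes in 99%, by Fisher's exact test without adjustment. The calls of the gene lists used adjusted p-values, so their detection rate is lower, and lists of fewer than 30 genes were not simulated.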

Results

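Binding of Hsf, the transcription factor that activates the heat shock genes of Drosophila melanogaster, was mapped in whole embryos aged 0 to 24 h that carried Hsf fused to GFP. The 3 samples were biological replicates of 1 group, and the labels named no heat treatment, so the comparisons were made among regions and genes within this group. The authors' optimal list held 5756 peaks in dm6, which covered 2060 kb and made up 19.2% of the 30000 pooled candidate regions. The background for the comparisons was the 23208 candidate regions that overlapped no optimal peak. Signal values are the authors' own, from the pooled list unless a replicate is named, and are used only for ranks and description. The number of reads behind each region is unknown.

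The strongest optimal peak lay upstream of CG14100 (3L:19590395-19590834, intergenic, 95 bp from the TSS) with a signal of 3523, and it ranked 2, 1 and 1 in replicates 1, 2 and 3. The next lay 1399 bp upstream of the TSS of cbt, which encodes a zinc finger transcription factor, in an intron of another gene (2L:480851-481334, signal 3236, ranks 1, 2 and 2). Other peaks among the strongest 20 lay within 500 bp of a TSS of Chro, which encodes a chromodomain protein (3L:22878690-22879126, in the 5' UTR, signal 2480), Ugalt, a UDP-galactose transporter gene (X:2703686-2704108, intergenic, 2414), Art3, an arginine methyltransferase gene (3R:15229319-15229762, intergenic, 2392), and px, a gene of wing vein patterning (2R:22514089-22514514, in an intron, 2340). Tcs5, the mitochondrial ribosomal protein gene mRpL41, lncRNA:CR44619, the Polycomb group gene ph-p, CenG1A, the mitochondrial exoribonuclease gene PNPase, CG8320, CG1888, the tubulin acetyltransferase gene Atat and CG9147 also had a promoter peak among the 20. The peaks nearest to CG11050, the kinase gene Lk6 and the HMG box gene HmgZ lay in introns, and that nearest to CG13323 was intergenic, 11907 bp from its TSS. In all, 15 of the 20 were promoter peaks, 4 intronic and 1 intergenic. A heat shock element as defined here lay within 100 bp of the summit in 2, those at px and lncRNA:CR44619. The 20 peaks had signals of 1704 or more, and their lowest rank was 50 in replicate 1, 27 in replicate 2 and 26 in replicate 3. With promoters taken as 200 bp from a TSS, px, lncRNA:CR44619 and CG1888 no longer held a promoter peak, and the peak counted for ph-p was a weaker one (signal 150).

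Of the 18 heat shock inducible genes, 7 had an optimal peak within 500 bp of a TSS, 5 had a candidate region that did not pass IDR and 6 had no candidate. The highest signal was at Hsp83, which encodes the fly Hsp90 (FBgn0001233, 3L:3192856-3193290, in the 5' UTR), where it was 1194, rank 55 in the pooled list and 19, 397 and 56 in replicates 1, 2 and 3. Hsp27, a small heat shock protein gene, had a peak of signal 695 (3L:9383759-9384064, intergenic, rank 203), and Hsp26, another, one of 368 (3L:9377456-9377665, intergenic, rank 768). The peak at lncRNA:Hsromega, a noncoding RNA gene that is induced by heat, had a signal of 355 (3R:21296156-21296495, in an exon, rank 825). Weaker peaks lay at the co-chaperone gene DnaJ-1 (3L:5752153-5752568, intergenic, 206), at stv, a BAG domain co-chaperone gene (3L:13476918-13477333, intergenic, 199), and at Hsp22 (3L:9373348-9373763, in the 5' UTR, 162). Among the 7 peaks, those at Hsp83 and lncRNA:Hsromega held a heat shock element as defined here, within 100 bp of the summit. Sites farther from the summit or in other arrangements were not counted, so the other genes may still have an element. Candidates at Hsp23 (3L:9381580-9381995, signal 82.8, rank 6897) and Hsp68 (3R:24057217-24057632, signal 54.2) held the element but were below the lowest optimal signal of 97. The candidates at Hsp67Ba (26.5) and at the shared upstream region of Hsp67Bc and CG4456 (31.8) held none.

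Across the cluster of small heat shock genes on 3L, 11 candidate regions and 4 optimal peaks lay within 18.2 kb, the latter at Hsp22, Hsp26, Hsp27 and the start of Fdx1, a ferredoxin gene next to the list's members (3L:9370873-9371288, signal 104). Fdx1 was singled out after its value was seen. No candidate lay within 500 bp of a TSS of the 6 Hsp70 genes, Hsp70Aa, Hsp70Ab, Hsp70Ba, Hsp70Bb, Hsp70Bbb and Hsp70Bc, which encode the major inducible chaperone, and the nearest candidate summit was 780 bp from Hsp70Aa. These copies are nearly identical, so their values are uncertain (a median of 11.1% of the 50-mers around their TSSs occurred once in the genome). Hsf itself had a candidate in its 5' UTR (2R:18134384-18134799, signal 38.8, rank 16279) that was not an optimal peak. The share of the list with an optimal peak, 7 of the 12 genes with a candidate (58.3%, 95% interval 32.0 to 80.7), did not differ detectably from the 42.9% of other genes (odds ratio 1.86, 0.509 to 7.46; Fisher's exact test, p = 0.383, adjusted p = 0.465). In the 3 replicates' own lists the share was 58.3% ± 8.33 (SD, n = 3). The peak at Hsp22 ranked 7012 in replicate 2, outside the top 5756, and without replicate 1 or replicate 3 the gene no longer had a recovered peak. With a TSS window of 200 bp, Hsp22, lncRNA:Hsromega and stv no longer had an optimal peak.

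**Figure D1:**
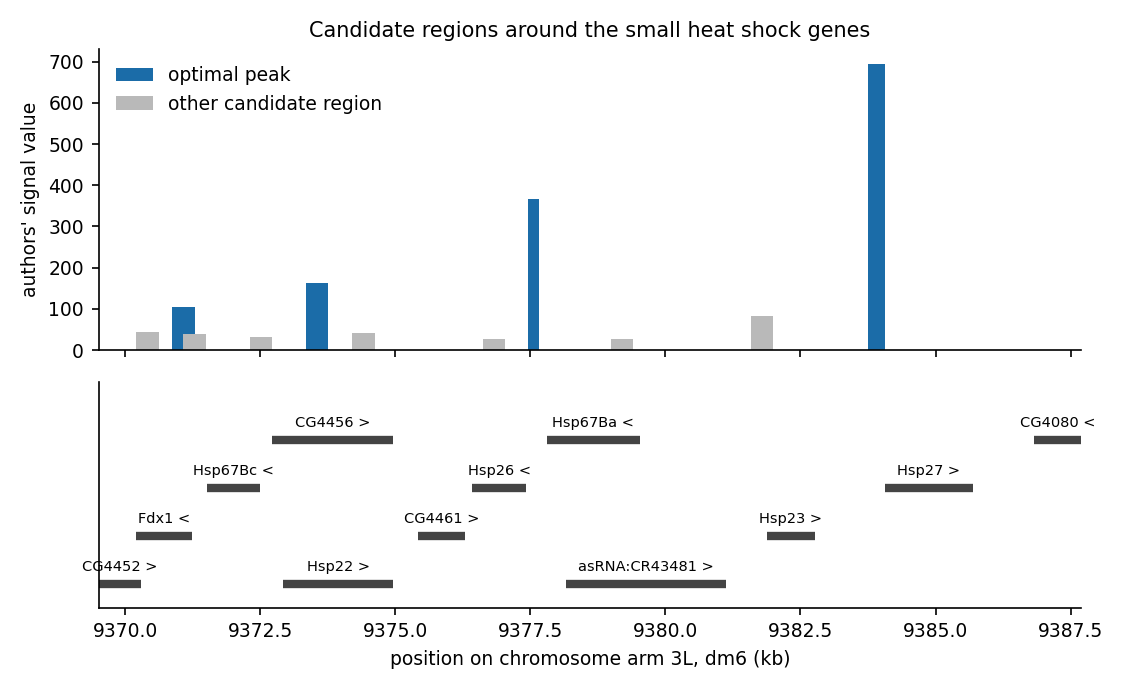
Candidate regions along 18.2 kb of chromosome arm 3L in dm6 (horizontal axis, kb), each drawn from its start to its end at the height of the authors' signal value, with optimal peaks in blue and other candidates in grey, and genes below with arrows for their strand. The peak at Hsp27 has a signal of 695 and that at Hsp26 one of 368, whereas the candidates at Hsp23, Hsp67Bc and Hsp67Ba are between 26.5 and 82.8.

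The heat shock element, the inverted repeat of GAA units through which Hsf binds DNA, was found within 100 bp of the summit in 356 of the 5756 optimal peaks (6.18%, 95% interval 5.59 to 6.84) and in 4.94% of background regions. The odds ratio was 1.27 (1.12 to 1.44; Fisher's exact test, two-sided, p = 0.000174). Among each replicate's strongest 5756 regions the share was 6.06% ± 0.216 (SD, n = 3), against 4.67% ± 0.363 in the rest of its list. The element without a mismatch occurred in 19 optimal peaks (0.330%) and 50 background regions (0.215%), and this difference did not pass the test (odds ratio 1.53, Fisher's exact test, p = 0.129). Of the 20 motifs with permuted columns, 8 had an odds ratio at or above that of the element, and their mean was 1.26 ± 0.150 (SD over 20 motifs). The windows at optimal summits had a mean GC content of 35.9%, those of the background 42.8%. Against candidates matched on GC content and promoter class the odds ratio was 1.09 (0.932 to 1.28; Fisher's exact test, p = 0.283). Against the candidates next in signal, a comparison chosen after seeing the data, it was 1.11 (Fisher's exact test, p = 0.220).

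Optimal peaks were ordered by signal to ask whether stronger peaks held the element more often. In the 1439 strongest peaks the share was 6.46%, in the next 1439 it was 6.95%, then 5.42%, and in the 1439 weakest 5.91%. Spearman's rho across peaks was 0.0171 (permutation test, two-sided, p = 0.194), and peaks are not independent replicates. With no mismatch allowed the sign turned, to −0.00552 (permutation test, p = 0.678).

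Of the 7 other motifs, those of DREF, M1BP and the TATA box, which are common at fly core promoters, were more frequent at optimal summits, and that of Zelda less. The site of DREF, a factor of cell proliferation genes, lay at 4.97% of optimal summits and 1.69% of background summits (odds ratio 3.04, 2.60 to 3.56; Fisher's exact test, two-sided, adjusted p = 4.29e-40). The TATA box was present at 16.1% and 10.1% (odds ratio 1.71; adjusted exact p = 1.44e-34), and the M1BP site, known from promoters of housekeeping genes, at 7.44% and 4.61% (odds ratio 1.66; adjusted exact p = 2.62e-16). The site of Zelda, the activator of the early zygotic genome, was less frequent at optimal summits (0.782% against 1.15%, odds ratio 0.674; adjusted exact p = 0.0222). Each of these directions held in 3 of 3 replicates, with DREF at 4.75% ± 0.396 of the top regions and 1.57% ± 0.292 of the rest (SD, n = 3). The motifs of GAGA factor (odds ratio 0.933), the E-box (0.833) and CTCF (1.01) did not pass the two-sided Fisher's exact test after adjustment. Against candidates matched on GC content and promoter class none of the 7 passed Fisher's exact test, with odds ratios of 1.26 for DREF (adjusted p = 0.0838), 1.02 for the TATA box, 1.01 for M1BP and 1.16 for Zelda, whose call was also lost without replicate 2 (adjusted p = 0.0554), above the median signal (0.0660) and within 50 bp of the summit (0.0778). Against the candidates next in signal, chosen after seeing the data, the odds ratios were 1.26 for DREF (adjusted exact p = 0.0461) and 1.22 for the TATA box (adjusted exact p = 0.00109), while M1BP (0.956, adjusted exact p = 0.854) and Zelda (1.00) did not pass. In strata of GC content and promoter class, chosen after seeing the data, DREF passed (common odds ratio 1.35, 1.15 to 1.59) and the other 6 did not. GAGA factor depended on the window, with an odds ratio of 0.591 (adjusted exact p = 0.000403) within 50 bp of the summit and 1.48 (adjusted exact p = 8.53e-16) within 250 bp. The E-box passed within 50 bp (0.658, adjusted exact p = 0.00871) and had an odds ratio of 1.02 within 250 bp.

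**Figure D2:**
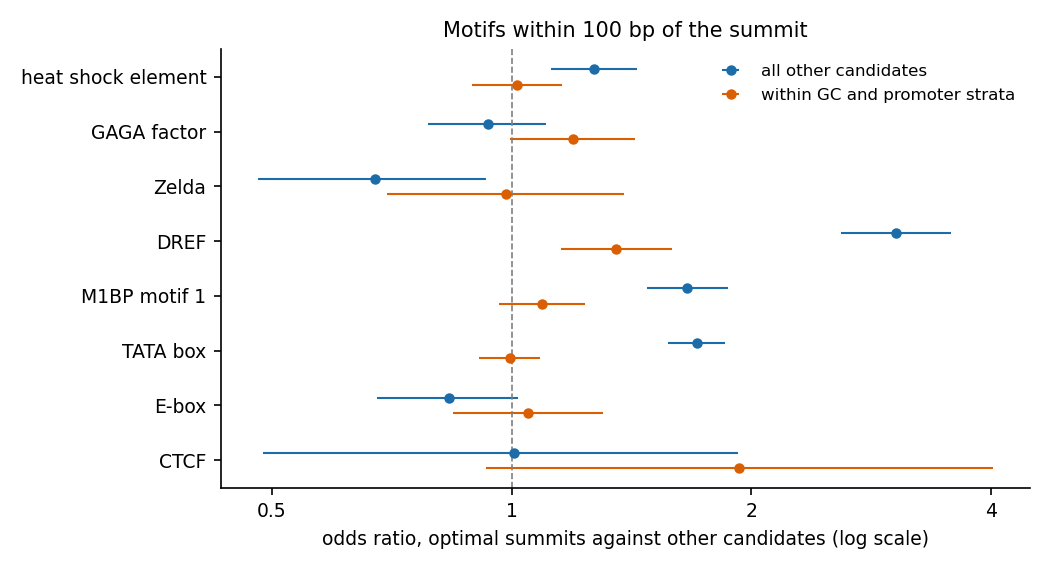
Odds ratio (log axis) of each motif at optimal summits against background candidates, and the common odds ratio within strata of GC content and promoter class, which was chosen after seeing the data; bars are 95% intervals. DREF moves from 3.04 to 1.35 and the heat shock element from 1.27 to 1.02.

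Optimal peaks were concentrated at promoters and nearly absent from coding sequence. Of the 5756 summits, 3020 (52.5%, 95% interval 51.2 to 53.8) lay within 500 bp of a TSS, against 26.8% of the background summits and 13.4% of the bases of the 6 arms. Only 8 summits (0.139%) lay in coding sequence outside promoters, against 12.0% of the background (odds ratio 0.0102, Fisher's exact test, adjusted p = 2.40e-266). Introns outside promoters held 32.4% of optimal and 38.0% of background summits (odds ratio 0.780, adjusted exact p = 1.75e-15), and intergenic sequence outside promoters 12.9% and 18.9% (odds ratio 0.635, adjusted exact p = 7.19e-28). Shares in 5' UTRs (0.417% against 1.01%) and 3' UTRs (0.747% against 2.34%) outside promoters were lower as well, and exons of noncoding transcripts did not differ detectably (0.956% against 0.875%, adjusted exact p = 0.583). Each summit counts in 1 class and promoters come first, so a higher promoter share by itself lowers the other shares. The classes were not compared among the summits outside promoters alone, so a lower share here does not mean avoidance of introns or intergenic sequence. The promoter share fell from 61.9% in the 1439 strongest peaks through 52.5% and 48.6% to 46.8% in the 1439 weakest. It was 52.6% ± 2.30 in the replicates' top regions and 25.7% ± 5.25 in the rest of their lists (SD, n = 3), higher in 3 of 3 replicates. The odds ratio for promoters was 3.01 (2.84 to 3.20; Fisher's exact test, two-sided, p = 1.58e-289). It was 1.75 against the candidates next in signal, chosen after seeing the data, and 6.92 against random positions.

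**Figure D3:**
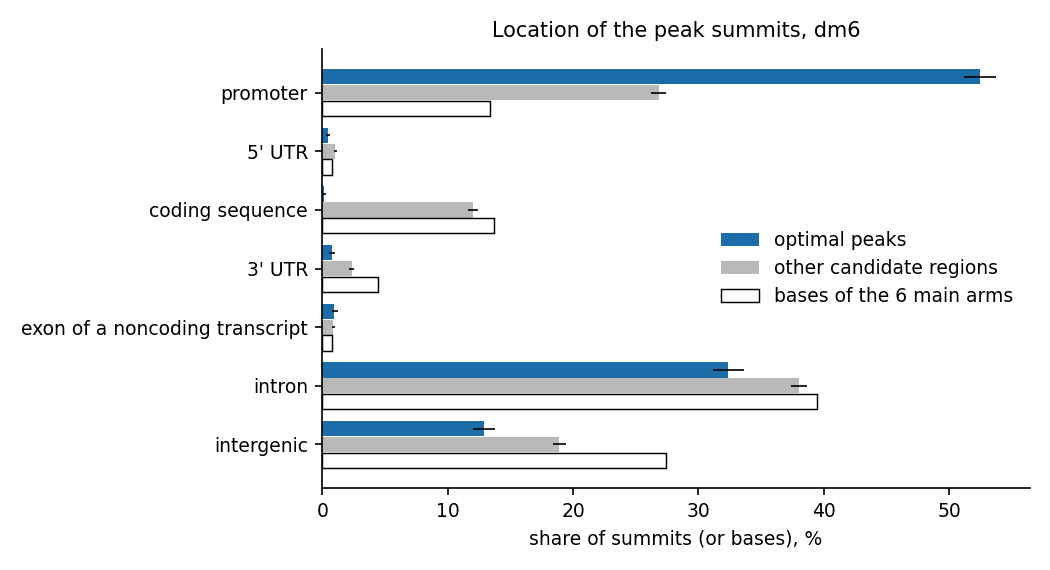
Share of summits (horizontal axis, percent) in each annotation class for the 5756 optimal peaks and the 23208 background candidates, beside the share of the bases of the 6 main arms, with 95% Wilson intervals for the peaks and candidates. Promoters hold 52.5%, 26.8% and 13.4%, and coding sequence 0.139%, 12.0% and 13.7%.

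Genes of the cytosolic ribosome had an optimal peak more often than other genes. Of the 85 ribosomal protein genes, 83 had a candidate region within 500 bp of a TSS and 71 of these (85.5%, 95% interval 76.4 to 91.5) an optimal peak, against 42.5% of other genes. The highest signals were at RpS27 (3R:25247355-25247723, intergenic, signal 940, rank 103), RpL7 (2L:10200874-10201193, in the 5' UTR, 915), RpL34b (3R:9401139-9401559, intergenic, 730) and RpL23A (3L:1668604-1668910, intergenic, 649). The odds ratio was 8.0 (4.30 to 16.2; Fisher's exact test, two-sided, p = 1.01e-15, adjusted p = 1.71e-14). In the replicates' own top regions the share was 84.3% ± 5.25 (SD, n = 3), from 81.9%, 80.7% and 90.4%. With all annotated genes as background the odds ratio was 18.5.

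Chaperone genes outside the heat shock list had an optimal peak in 18 of the 26 with a candidate (69.2%), and proteasome genes in 19 of 28 (67.9%). The chaperone genes with the highest signals were mrj, a DnaJ family gene (2R:16206350-16206710, in an intron, signal 1014, rank 82), the mitochondrial Hsp70 family gene Hsc70-5 (384), CG11267, an Hsp10 family gene (319), and Hsc70-4, the constitutive cytosolic Hsp70 gene (283). In the proteasome list they were the regulatory particle subunit genes Rpn5 (3R:5788999-5789295, upstream of it in an intron of another gene, signal 519, rank 385, but 227 within 200 bp of a TSS), Rpn3 (461), Rpn6 (299.9) and Rpn13 (226). The odds ratios were 3.00 (1.24 to 7.99; Fisher's exact test, two-sided, adjusted p = 0.0376) for the chaperones and 2.82 (1.21 to 7.08; adjusted p = 0.0391) for the proteasome. The settings without 1 replicate kept the pooled peaks found in the top N of both others, a stricter filter. By the same exact test, the chaperone call was lost without replicate 1 (odds ratio 2.22, adjusted p = 0.234) and without replicate 2 (2.20, adjusted p = 0.232), and the proteasome call without replicate 1 (1.43, adjusted p = 0.603), 2 (1.41, adjusted p = 0.578) or 3 (1.76, adjusted p = 0.354). Both were also lost with a TSS window of 200 bp, among the peaks above the median signal, where the proteasome odds ratio was 0.990, among peaks found in all 3 replicates (2.20 for chaperones and 1.22 for the proteasome) and against the candidates next in signal (1.54 and 2.85). They were kept with 1000 bp (3.01 and 2.82) and with all annotated genes as background (4.99 and 5.27).

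Among genes with a candidate, those of tRNAs and of chemoreceptors had an optimal peak less often than other genes. Of 138 tRNA genes with a candidate, 20 (14.5%, 95% interval 9.58 to 21.3) had an optimal peak, against 43.3% of other genes. The highest signals near tRNA genes were 848 at tRNA:Tyr-GTA-1-8 (3R:8669199-8669549, outside it in an intron of another gene), 404 at tRNA:Gln-TTG-2-1 and 363 at a peak shared by tRNA:Asp-GTC-1-5 and tRNA:Asp-GTC-1-4. The odds ratio was 0.222 (0.130 to 0.359; Fisher's exact test, two-sided, adjusted p = 7.11e-12), and it was 0.0945 with a TSS window of 200 bp and 0.351 with one of 1000 bp. The test counted each gene separately although tRNA genes can share a region, so its p-value and interval may overstate the precision. The share of sequence that occurs once in the genome was not counted for the tRNA genes as a list. An effect of reads shared between copies on their low share was therefore not tested. Among the 119 olfactory and gustatory receptor genes, 15 had a candidate and 1, the carbon dioxide receptor gene Gr63a (3L:3896710-3897125, upstream of it in the 5' UTR of another gene, signal 99.7), an optimal peak (odds ratio 0.0949, 0.00224 to 0.624; Fisher's exact test, adjusted p = 0.0190). The region of Gr63a had no counterpart in the list of replicate 2, and without replicate 2 the call for the list was lost (odds ratio 0.134, adjusted exact p = 0.150). By the same exact test it was also lost above the median signal (adjusted p = 0.0976), with a TSS window of 200 bp (adjusted p = 0.506) and against the candidates next in signal (odds ratio 0.299, adjusted p = 0.960), and kept with 1000 bp (0.253, adjusted p = 0.0374) and with all annotated genes as background (0.0302, adjusted p = 6.54e-11).

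The remaining lists did not pass the test. The ecdysone list had optimal peaks at 5 of 12 genes with a candidate, including Ldh, the lactate dehydrogenase gene (3L:6262681-6263085, intergenic, signal 531), and the nuclear receptor gene Eip75B (474). Autophagy genes had them at 10 of 16, including Atg17 (607, or 329 within 200 bp) and Atg2 (437, or 238 within 200 bp), cell cycle genes at 13 of 23, including the replication helicase gene dpa (353) and the mitotic kinase gene aurA (331), and germline genes at 5 of 8, including bgcn (349) and piwi (272). Of the stress genes 9 of 20 had one, including Keap1 (257, or 576 within 1000 bp) and cnc (235), the repressor and the activator of the oxidative stress response. Muscle genes had them at 3 of 14, with Msp300 at 750 and sls at 559, neuronal genes at 3 of 9, with elav at 988 and scrt at 170, and segmentation genes at 2 of 12, bcd (326) and wg (101.1). The peak at wg ranked 7386 in replicate 2 and 7436 in replicate 3, and without any 1 replicate it was not recovered in both others. No optimal peak lay at the 5 Hox, 6 chorion and yolk or 3 antimicrobial peptide genes with a candidate, although the top regions of each of the 3 replicates included 20% of these Hox genes. Adjusted p-values ran from 0.116 for chorion and yolk genes to 1 (Fisher's exact test, two-sided). With all annotated genes as background, autophagy (odds ratio 4.00, adjusted exact p = 0.00753) and cell cycle genes (4.25, adjusted exact p = 0.00148) passed as well.

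**Figure D4:**
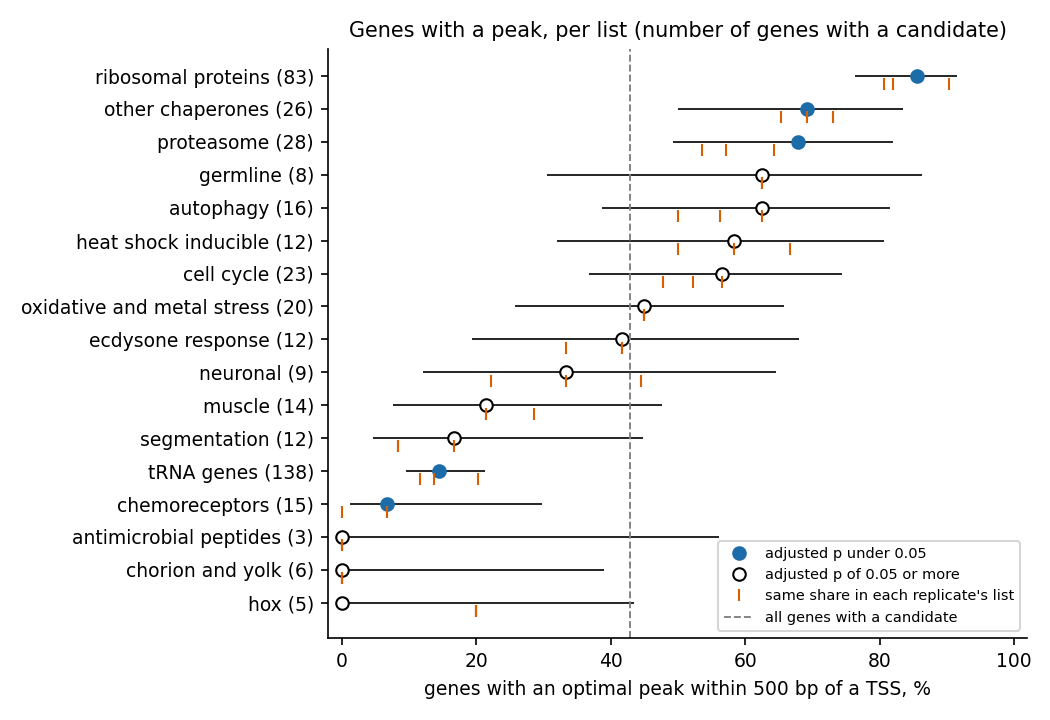
Percent of genes with an optimal peak within 500 bp of a TSS (horizontal axis) among the genes with a candidate, for each of the 17 gene lists, with 95% Wilson intervals, the share of all genes with a candidate (42.9%) as a line, and orange ticks for the top 5756 regions of each of the 3 replicates. Ribosomal protein genes stand at 85.5% and tRNA genes at 14.5%.

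The arms of the genome held optimal peaks and background candidates in similar shares. The X chromosome had 1069 optimal peaks (18.6%), against 17.0% of the background and 17.6% of the genome (odds ratio 1.11, 1.03 to 1.20; Fisher's exact test, two-sided, adjusted p = 0.0389). The arms 2L (odds ratio 0.988), 2R (0.954), 3L (0.920), 3R (1.05) and 4 (0.652) did not pass the test. The call for X was lost without replicate 2 (odds ratio 1.06, adjusted exact p = 0.397) and among peaks found in the top regions of all 3 replicates (1.11, adjusted exact p = 0.0665), and without replicate 3 arm 4 passed as well (0.489, adjusted exact p = 0.0315).

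The 3 replicates ranked largely the same regions highest. Of each replicate's strongest 5756 regions, 76.9% were shared between replicates 1 and 2, 77.2% between 1 and 3 and 78.4% between 2 and 3 (77.5% ± 0.814, SD over 3 pairs), whereas 100 circular shifts gave at most 3.77%. The shifts do not keep regions at promoters, so they give the level of random placement only. The optimal list was made from these 3 replicates, so a high recovery of its peaks in each of them is partly built in. Optimal peaks were found among the strongest 5756 regions of replicate 1 in 86.3%, of replicate 2 in 86.5% and of replicate 3 in 85.3%. All 3 replicates recovered 3909 optimal peaks (67.9%), and 16 were in the top regions of none. Recovery in all 3 was 99.8% among the 1439 peaks of highest pooled signal, 95.8% among the next 1439, 62.0% among those that follow and 14.1% among the 1439 weakest. Because recovery requires a place in the top 5756 of each replicate, peaks near the cut in the pooled list easily fall out. In the full lists of replicates 1, 2 and 3, a region overlapped 99.3%, 98.7% and 99.7% of the optimal peaks. Across optimal peaks, Spearman's rho of the signal was 0.708 between replicates 1 and 2, 0.733 between 1 and 3 and 0.792 between 2 and 3 (0.745 ± 0.0427, SD over 3 pairs).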

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

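The tests in strata of GC content and promoter class, of the permuted motifs and of ribosomal protein genes without the element were chosen only after the results were seen, as was the rule that an interval should exclude the uncorrected odds ratio. Regions outside the 6 main arms appear in the dm3 lists, which served only as alternatives for the number of peaks and the comparison of replicates: 34 in the list of replicate 1, 204 in that of replicate 2, 75 in that of replicate 3 and 49 in the pooled list. Each is above 3, the limit set for flagging a count, and no excess was tested. Of these, 28, 183, 69 and 39 lie on heterochromatin scaffolds and the others on unplaced sequence. The optimal dm3 list held 3 such regions, no more than that limit, on heterochromatin scaffolds.

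The heat shock element was more frequent at optimal summits than at other candidates (odds ratio 1.27), and the peak windows were lower in GC content (35.9% against 42.8%). Base composition is a candidate explanation that the tests leave standing: the odds ratio was 1.09 (0.932 to 1.28) against candidates matched on GC content and promoter class, and 1.02 with all candidates kept in strata (0.892 to 1.16, an interval that excludes 1.27). Motifs with the same bases in another order were raised as well, 8 of 20 at or above the element. The odds ratio of summit windows against windows 1000 bp away was 1.19 (1.04 to 1.37) for the element. Over the permuted motifs it had a median of 1.25 (0.810 to 1.71, lowest to highest), and 13 of the 20 were at or above the element. A value at or below that median was the outcome set in advance as counting against binding through the element as what places the peaks. The interval of the element includes the median, so this test cannot decide whether binding through the element places the peaks. A definition of the element by 3 GAA units leaves other arrangements of the site uncounted, and no biological explanation other than binding through the element was tested.

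Ribosomal protein genes held optimal peaks more often than other genes (85.5%, odds ratio 8.0). The number of annotated TSS positions, counted up to 5 and with a mean of 1.75 in these genes and 1.5 in others, is argued against as the whole cause by a common odds ratio of 7.94 (4.24 to 14.9) over strata of that number. Base composition around the TSS is argued against by a mean GC content of 42.3% in these genes and 42.4% in others, which left little to correct, and the common odds ratio over strata of GC content was 7.5 (4.06 to 13.8). The heat shock element as defined here is also argued against as the whole cause: 4 of 71 peaks of these genes held it, and among genes with no element at any candidate near a TSS, 66 of 77 ribosomal protein genes and 41.7% of other genes had an optimal peak (odds ratio 8.37, 4.38 to 17.6; Fisher's exact test, p = 3.04e-15). Other properties of these promoters, such as their transcription level in the embryo or open chromatin, were not analysed here and stay open.

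No candidate region lay within 500 bp of the TSSs of the 6 Hsp70 genes. Reads shared between the near-identical copies are a candidate explanation: a median of 11.1% of the 50-mers within 250 bp of their TSSs occurred once in the genome (0 to 46.7%), against at least 92.5% at the 12 other heat shock genes. Over all annotated TSS positions, 10 of 537 with under 50% unique 50-mers held a candidate (1.86%), against 51.7% of the others (odds ratio 0.0177, 0.00844 to 0.0329, Fisher's exact test, p = 1.37e-146). The length of the reads and how the authors treated reads with several matches are not given in the sources used here. Whether Hsf occupied these genes in the embryos stays open, and no biological explanation was tested.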

How the results depend on the processing

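The candidates next in signal and the strata of GC content and promoter class were chosen only after the results were seen, and the other alternatives were planned. Leaving aside the signals of single peaks, 234 of 318 alternative values were classed as unchanged. They kept their direction and side of the threshold, moved by less than the spread between replicate pairs or, for counts, stayed within a fixed ratio of the main count. The last rule covers 7 numbers of optimal peaks and counts of motifs (7), lists (3) and arms (1) past the threshold, some of which differ from the main count. Of the unchanged values, 120 were odds ratios of single gene lists. Only 5 of the 17 lists passed the main test, so most of these values had no call to lose. The promoter odds ratio kept its direction and call in its 9 alternatives (1.75 to 6.92), as did the list of ribosomal proteins (6.09 to 18.5) and that of tRNA genes (0.0945 to 0.351). The number of optimal peaks stayed between 3909 and 5756. Replicate overlap was 79.0% for the top 1000 regions, 70.01% for 2 times N, 56.8% for all regions, 70.5% for summits within 100 bp, 67.2% for 50% reciprocal overlap and 76.9% to 78.4% without 1 replicate. Signal correlation was 0.798 as Pearson's r of log2 signal and 0.708 to 0.792 without 1 replicate. The heat shock element lost its call with no mismatch (1.53, fewer regions), with matched candidates (1.09), candidates next in signal (1.11) and strata (1.02), and its trend with signal turned to −0.00552 with no mismatch. Among arms past the threshold there were 0 above the median signal, 0 in peaks of all 3 replicates and 0 to 2 without 1 replicate; 2L, never past it, turned to 1.05 above the median, 1.00 in peaks of all 3 replicates and 1.01 without replicate 2 or 3, but not without replicate 1 (0.984). Of the 7 motifs, 0 passed with matched candidates, 2 against candidates next in signal, 1 in strata and 5 with 50 or 250 bp windows, where the E-box passed within 50 bp (0.658). Directions turned with matched candidates for GAGA factor (1.14), Zelda (1.16) and the E-box (1.07), in strata for GAGA factor (1.19), the TATA box (0.995) and the E-box (1.05), with 250 bp windows for GAGA factor (1.48), the E-box (1.02) and CTCF (0.697), and next in signal for M1BP (0.956). Lists past the threshold numbered 2 above the median signal, 3 in peaks of all 3 replicates, 2 to 4 without 1 replicate, 2 with 200 bp and 2 next in signal. Odds ratios of lists turned above the median signal for the proteasome (0.990), stress (0.990), germline (0.990) and cell cycle (0.825), with 200 bp for stress (0.818) and ecdysone (1.36), next in signal for stress (0.896) and segmentation (1.20), and for ecdysone in peaks of all 3 replicates (1.10), over all annotated genes (1.38) and without replicate 3 (1.01), but not without replicate 1 or 2 (0.940 at the lowest). Odds ratios could not be computed for antimicrobial peptides with 200 bp and next in signal, nor next in signal for chorion and yolk or germline genes. Apart from the fewer regions or genes that the stricter settings leave, the cause was not tested. Of the 55 named genes with a peak, 52 kept one in the stricter sets (54 without replicate 2), where Hsp22, wg and Gr63a were lost, 38 with 200 bp and 55 with 1000 bp. The signal counted changed with 200 bp at Rpn5 (227), Atg17 (329), Atg2 (238) and ph-p (149.7), and with 1000 bp at Keap1 (576) and stv (253). Depth is unknown, so its effect on the weaker peaks cannot be judged here.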

Other observations

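Both tests of this part were chosen only after the result was seen. Among the strongest peaks were 4 at genes of the mitochondrial ribosome: the promoter peak shared by mRpS10 and Art3 ranked 6 (3R:15229319-15229762, signal 2392), that of mRpL41 ranked 9 (2R:15217566-15218007, 2313), that shared by mRpS23 and CenG1A ranked 12 (2L:13835255-13835667, 2039) and that of mRpL23 ranked 33 (3L:2373418-2373795, 1447), while the next, at mRpL24, ranked 383. Of the 63 mitochondrial ribosomal protein genes with a candidate, 40 (63.5%) had an optimal peak, against 42.8% of other genes (odds ratio 2.33, 1.36 to 4.08; Fisher's exact test, two-sided, p = 0.00124). In the replicates' own top regions the share was 59.8% ± 3.99 (SD, n = 3). The list was made after these genes had been seen among the strongest peaks, so the value is a hypothesis to be tested on other data.

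Among 9-base words within 50 bp of the summits, AGATGGCGC ranked highest on the arms X, 2L and 2R, at 35 optimal summits and 7 candidates matched on GC content and promoter class. On the other arms it lay at 24 of 2563 optimal summits and 6 of 2536 matched candidates (odds ratio 3.98, 1.58 to 11.9; Fisher's exact test, two-sided, p = 0.00139, adjusted over 10 words 0.00697). The overlapping words GATGGCGCC (odds ratio 13.9, 2.11 to 589; adjusted exact p = 0.00697) and CAGATGGCG (4.97, 1.40 to 26.8; adjusted exact p = 0.0248) also passed. The similar word AGGTGGCGC, ranked 2, did not (15 against 6 summits, odds ratio 2.48, 0.908 to 7.82; adjusted exact p = 0.195), nor did the remaining 6 words. Both AGATGGCGC and AGGTGGCGC lie in the core of the site known for the insulator protein CTCF, while the stricter CTCF motif of the report occurred at only 12 optimal summits. Its odds ratio was 1.01 (0.487 to 1.93) against background and 3.00 (0.910 to 12.8) against matched candidates, and neither interval excludes 1. In all AGATGGCGC lay at 59 optimal summits, 33.9% of them at promoters. A small set of the peaks may therefore coincide with insulator sites (odds ratio 3.98), a hypothesis only, because AGATGGCGC had been seen on all arms before the arms were separated.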
